A study of Mus musculus with 6 samples.

How the data were processed

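RNA was measured by sequencing in 6 samples of mouse embryonic fibroblasts (MEFs, primary connective tissue cells grown from embryos) of the C57BL/6 strain. The libraries fell into 3 from cells given p27 by lentivirus (p27OE) and 3 labelled EV control, all at day 10. The EV control titles carry a dataset tag that the p27OE titles lack, and the labels do not say whether the groups were prepared or sequenced together. Per the labels' protocols, RNA was extracted on columns (RNeasy Micro kit) and libraries were made with the TruSeq RNA Library Prep Kit v2. Per the submitters' processing notes, the tools named were TopHat2 2.0.14, Bowtie2 2.2.6, featureCounts 1.4.6 and Subread, with the mm10 genome. The annotation, the strand setting and any filter were not given in the sources used here. The deposited table holds whole-number read counts per gene symbol, not normalised by the authors. No row was a blank or a total, and 0 rows were mitochondrial genes, so a mitochondrial share was not measured here. Without a stated strand setting, overlapping and antisense genes share counts in an unknown way, and near-identical gene copies may share or lose reads.

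Library totals ran from 39183624 to 61219345 counts. The table had 24062 symbols, of which 5856 had no count in any library. edgeR's filterByExpr left 13990 genes, which held 99.976% of all counts. Every column matched 1 sample by its title. Within groups, a chi-square per gene between libraries lay between 6.53 and 189.34, so no library repeated another within sampling noise.

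Counts were scaled by TMM factors and tested with edgeR 4.0.16 (glmQLFit with robust estimation, glmQLFTest, two-sided) in R 4.3.3, with the group as the only term. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, and a gene was called at an adjusted p under 0.05. Standard errors belong to the log2 fold changes of the same model. CPM, the count of a gene scaled to the size of its library, was computed from the deposited counts with the TMM factors. A prior count of 2 was added for log2 CPM. Gene lists were written before the data were examined, 27 in number, and the 25 with at least 3 tested members were tested with camera (limma 3.58.1, voom values, preset correlation of 0.01), with adjustment over the lists. Cdkn1b itself was left out of the list tests. Camera with an estimated correlation, and fry, were run beside it. Members were also adjusted over the list alone. The mitochondrial and erythroid lists had too few tested members.

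The genes named were fixed by a rule before the data were examined. It took Cdkn1b and 12 cell cycle, senescence and secreted factor genes. It added the 10 largest called changes in each direction with a mean log2 CPM of at least 2, no overlap between groups and no predicted gene symbol. From each list it took the 3 members with the smallest p (2 for quality and cell type lists). All 92 such genes matched GENCODE M21 (GRCm38, the same assembly as mm10) by exact symbol, which gave the coordinates. Of the genes fixed by name, 1 is not reported here.

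The alternatives chosen before the data were examined were RLE, upper-quartile and total-count scaling, no filter, a stricter filter (1 CPM in 3 libraries), DESeq2 1.42.0, limma-voom, the replicate number as a block, Cdkn1b left out, and each library left out in turn. After the data were seen, these were added: the Y-linked level of each library as a term (summed CPM of Ddx3y, Eif2s3y, Kdm5d and Uty, as a share of the highest library), the same with an estimated correlation, and both libraries numbered 1 left out. Reactome sets (fgsea's mouse file, 10 to 300 tested genes) were also run after the data were seen: 30 of 834 sets were higher and 209 lower with camera, and 0 passed with an estimated correlation, so no Reactome set is named.

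The design was tested on simulated counts with 200 changed genes. At the spread of these libraries, over 13828 genes, 9% of genes changed 1.5-fold, 74.6% changed 2-fold and 98.5% changed 4-fold were called, and 14 of 135 calls were false. With the Y-linked level as a term, over 13880 genes, those shares were 89.6%, 98.5% and 100%, and 16 of 208 calls were false. In both runs the share of false calls was above 0.05, the share that the threshold aims at. The changed genes were drawn from those with a mean CPM above 4. Each gene was drawn independently, and no effect of the Y-linked level was put in. The run with that term therefore shows only the smaller spread, not how a term chosen after seeing the data behaves. The labels do not say that the 3 samples of a group came from separate cultures, embryos or transductions, so p-values measure only the spread between these samples. It may be partly technical. Summed Y-linked CPM was 0.13, 126.07 and 124.43 in EV control 1, 2 and 3 and 1.95, 57.15 and 137.26 in p27OE 1, 2 and 3. These values argue against a purely technical spread, except between EV control 2 and 3.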

Results

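Messenger RNA was counted at day 10 in mouse embryonic fibroblasts given p27 by lentivirus and in EV control cells, with 3 libraries per group. The protein p27 is the cyclin-dependent kinase inhibitor encoded by Cdkn1b. The EV control libraries held 39183624, 61219345 and 46140066 counts, and the p27OE libraries 44651036, 48014367 and 43621464 counts. The series design text describes the cells as non-senescent, while the treatment protocol and the p27OE sample titles call them senescent; the data were compared under the group names alone. The comparison asks which transcripts differ in cells with raised p27.

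Cdkn1b rose in p27OE cells, from 35.9 ± 6.93 CPM to 245 ± 85.9 CPM (SD, n = 3 each). Every p27OE library, at 167, 232 and 337 CPM, lay above every EV control library, at 43.9, 31.5 and 32.3 CPM. The log2 fold change was 2.77 ± 0.29 (SE; edgeR adjusted p = 0.028). The gene lies on chromosome 6 at 134920401 to 134925513 (GRCm38). The counts do not separate endogenous from introduced transcripts. The call held without EV control 1 (adjusted p = 0.0201) and was lost when any other single library was left out, with adjusted p from 0.0563 to 0.189 and a log2 fold change never below 2.48.

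**Figure D1:**
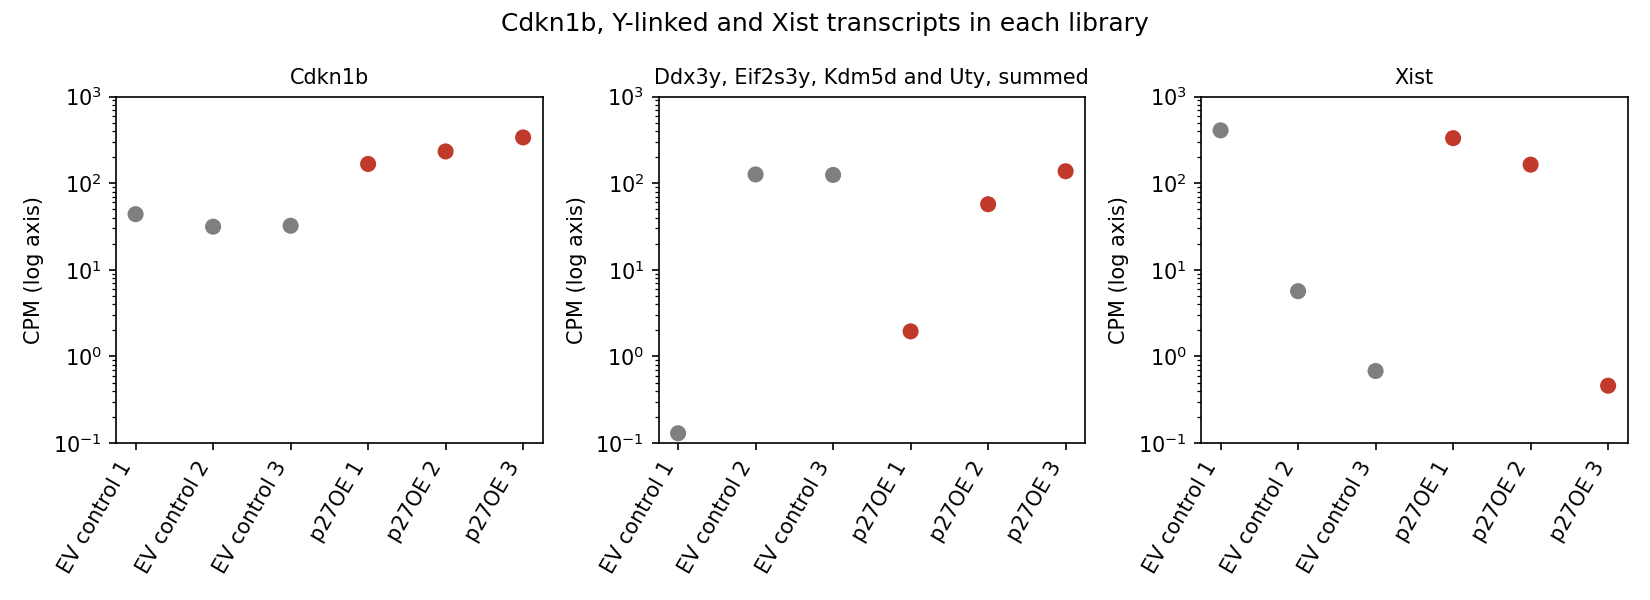
CPM of Cdkn1b (left), of 4 Y-linked genes summed (middle) and of Xist (right) in each of the 6 libraries, on a log axis. Grey points are EV control and red points p27OE. Cdkn1b separates the groups, while Y-linked CPM runs from 0.13 in EV control 1 to 137 in p27OE 3 across both groups.

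Beyond Cdkn1b, the largest called rise among genes with a mean log2 CPM of at least 2 was in Col10a1, the collagen X chain of hypertrophic cartilage (chromosome 10, 34389981 to 34397085), from 36.4 ± 3.05 to 229.5 ± 5.24 CPM (SD, n = 3), a log2 fold change of 2.66 ± 0.09 (SE; edgeR adjusted p = 0.0004). Grin3a, an NMDA receptor subunit, rose by 2.16 ± 0.22 on the log2 scale (SE), Perp, a p53 target of desmosomes, by 1.92 ± 0.17, and Kctd8 by 1.88 ± 0.16. Myom1, Serpinb9b, Tmem151a, Atp9a and Rgs5 rose by 1.79, 1.75, 1.64, 1.61 and 1.53. Rtkn2 fell by 1.51 ± 0.24 and Egln3, a prolyl hydroxylase induced by low oxygen (chromosome 12, 54178981 to 54203860), by 1.48 ± 0.15. Crabp1, a retinoic acid binding protein, fell by 1.45 ± 0.26, Plat, tissue plasminogen activator, by 1.23 ± 0.17, and Tgfbi by 1.22 ± 0.16. The histone chaperone gene Asf1b fell by 1.15, Pknox2 by 1.11, the kinesin gene Kif21b by 1.10, Cdc7, a kinase that starts DNA replication, by 1.08 and Ets2 by 1.07.

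In all, 365 of 13990 genes passed (edgeR, adjusted p under 0.05), 247 higher and 118 lower in p27OE cells, and 80 of them changed at least 2-fold, 62 up and 18 down. The groups did not overlap for 4653 genes, 33.3% of those tested, where chance gives 10%. Without EV control 1 the count was 1827; without any one of EV control 2, EV control 3, p27OE 1 or p27OE 2 it was 1, and without p27OE 3 it was 2. The share of higher calls was 67.7%, but 49.3% of 2321 with DESeq2, 47.6% of 1827 without EV control 1 and 46.7% of 2334 without both libraries numbered 1. Col10a1 kept its call in each of these.

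**Figure D2:**
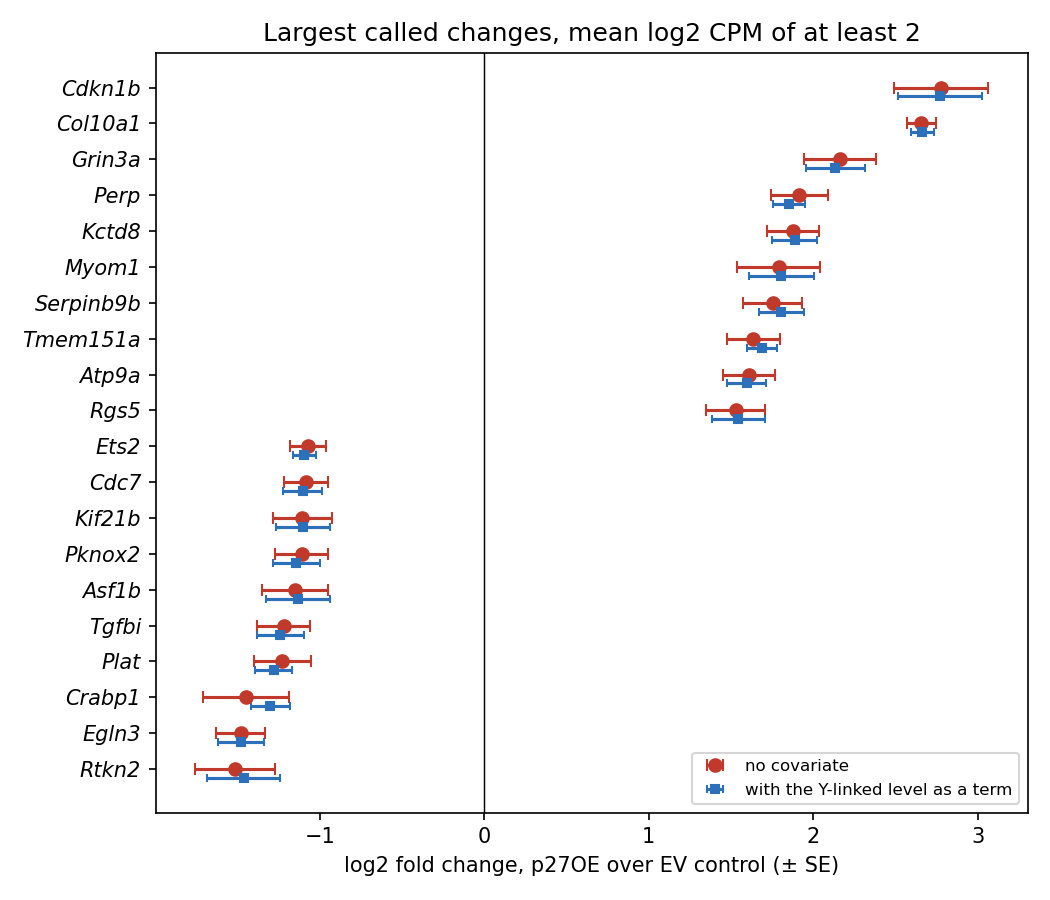
Log2 fold change of p27OE over EV control, ± SE, for the 10 largest called changes in each direction among genes with a mean log2 CPM of at least 2, n = 3 per group. Red circles are from the model with the group alone and blue squares from the model with the Y-linked level as a term; the points lie close together, with Cdkn1b at 2.77 in both.

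The libraries differed in transcripts from the sex chromosomes within both groups. Summed CPM of Ddx3y, Eif2s3y, Kdm5d and Uty was 0.13, 126.07 and 124.43 in EV control 1, 2 and 3, and 1.95, 57.15 and 137.26 in p27OE 1, 2 and 3. Xist, transcribed from the inactive X, went the other way, at 407, 5.67 and 0.68 CPM in the controls and 330, 164 and 0.46 CPM in p27OE. The first principal component (49.6% of the variance) set EV control 1 and p27OE 1 apart from EV control 2, EV control 3 and p27OE 3, with p27OE 2 between them, and the second (32.3%) separated the groups. With the Y-linked level as a term, chosen after seeing the data, 4761 of 13990 genes passed, 2517 higher and 2244 lower, including all 365. Counts of list members that rose or fell in this model are to be read against that share of all genes. In the low-level libraries, p27OE 1 against EV control 1, Cdkn1b differed by 1.92 on the log2 scale, and in the high-level ones, p27OE 3 against EV control 2 and 3, by 3.40; the 365 genes, called on these same libraries, had the same direction in both. Of all tested genes, 80.6% had the direction of the fold change over all 6 libraries in the low-level difference and 87.4% in the high-level one, and that fold change includes these same libraries.

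Transcripts of cell division were lower in p27OE cells. All 38 genes of the G2/M and mitosis list had a log2 fold change below 0, with a median of −0.89; 1 fell when adjusted over all genes, Bora, an activator of mitotic entry (−0.79 ± 0.13, SE; edgeR adjusted p = 0.045), and 38 fell when adjusted over the list alone. Ttk and Foxm1, a checkpoint kinase and a mitotic transcription factor, had values of −0.93 ± 0.19 and −0.93 ± 0.19 without passing. Mki67, a proliferation marker, was at 198 ± 6.97 CPM in EV control and 105 ± 34.4 CPM in p27OE (SD, n = 3), with a log2 fold change of −0.91 ± 0.24 (SE; edgeR adjusted p = 0.0769). In the G1/S and DNA replication list, 35 of 36 genes lay below 0 with a median of −0.67; 0 fell over all genes and 27 fell adjusted over the list alone. Pole, Cdc45 and Mcm3 had values of −0.73, −0.75 and −0.64. Camera gave the G2/M list an adjusted p of 4.99e-19 and the G1/S list 5.48e-14, and each had an adjusted p of 0.629 with an estimated correlation. In the model with the Y-linked level, 37 G2/M and 28 G1/S genes fell. The G2/M median difference was −0.38 between the low-level libraries and −1.49 between the high-level ones, and the G1/S difference was −0.25 and −1.13.

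**Figure D3:**
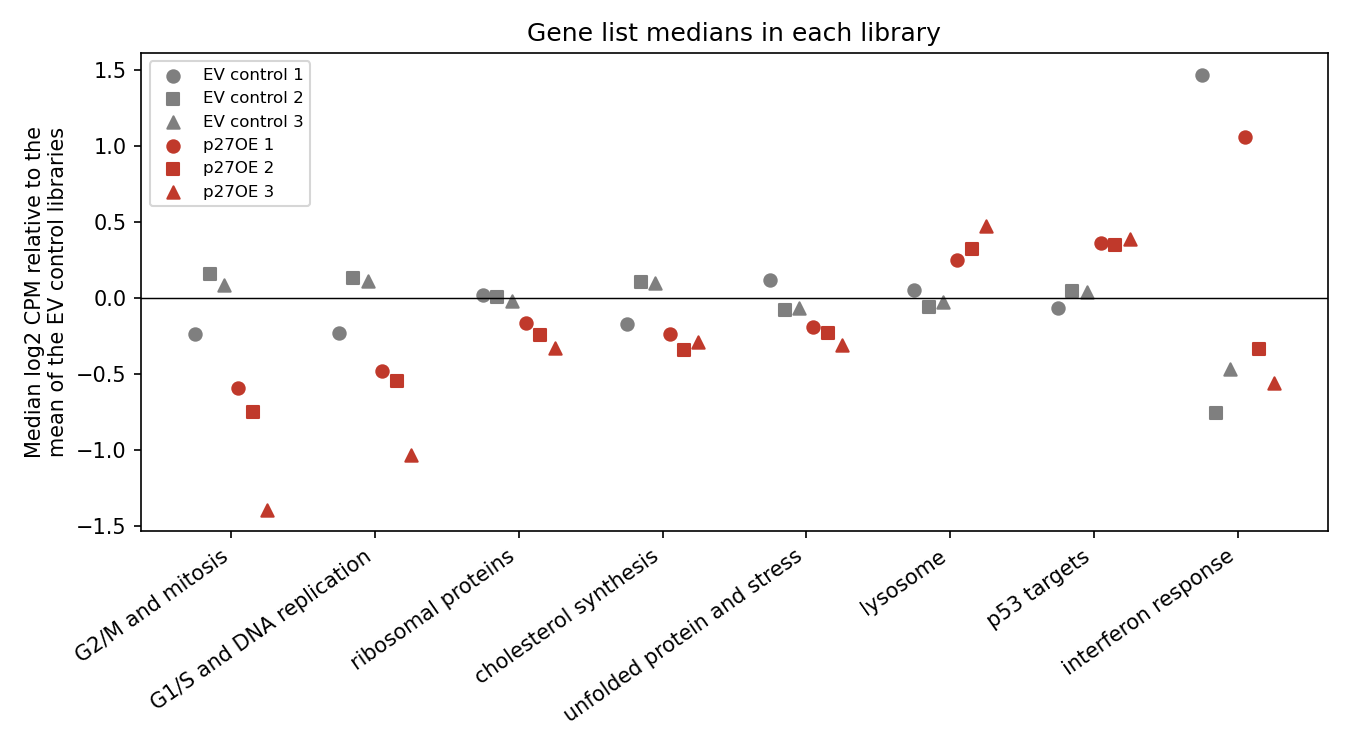
Median log2 CPM of 8 gene lists in each library, relative to the mean of the EV control libraries. Grey symbols are EV control and red symbols p27OE (circle, square and triangle for libraries 1, 2 and 3). The G2/M medians of p27OE lie between −1.396 and −0.597, and the interferon medians are highest in EV control 1 (1.47) and p27OE 1 (1.06).

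Genes of the lysosome were higher in p27OE cells, 31 of 34 above 0 with a median of 0.36; 3 rose over all genes and 19 rose adjusted over the list alone. Ctsd, the protease cathepsin D, rose from 527 ± 34.7 to 1051 ± 159 CPM (SD, n = 3; a fold change of 1.99; edgeR adjusted p = 0.0303). Ctsf and the fucosidase gene Fuca1 rose by 1.23 ± 0.21 and 0.37 ± 0.06 on the log2 scale. Of 26 p53 target genes, 22 lay above 0 with a median of 0.35; Perp and Phlda3 (0.67 ± 0.09) rose over all genes, and 9 rose and 1 fell adjusted over the list alone. Camera adjusted p was 1.31e-08 for the lysosome and 0.000173 for p53 targets, and adjusted p was 0.629 and 0.254 with an estimated correlation. With the Y-linked level as a term, 25 lysosome genes and 17 p53 targets rose and 1 p53 target fell.

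Cholesterol synthesis, ribosomal protein and stress response genes were lower. Of 24 cholesterol genes, 22 lay below 0 (median −0.34); the sterol transporter gene Stard4 and the synthesis enzyme genes Lss and Fdft1 fell, by 0.71 ± 0.12, 0.51 ± 0.08 and 0.46 ± 0.07 on the log2 scale (SE), and 8 fell adjusted over the list alone. Of 82 ribosomal protein genes, 81 lay below 0 with a small median of −0.25; 0 fell over all genes and 34 fell adjusted over the list alone, and Rpsa was at 2107 ± 39.3 CPM in EV control and 1598 ± 87.8 CPM in p27OE (SD, n = 3). Of the 23 genes of the unfolded protein and integrated stress responses, 19 lay below 0 and 4 above, with a median of −0.24. The chaperone gene Hspa5 was at −0.38 ± 0.11 and the serine synthesis gene Psat1 at −0.86 ± 0.22. Dnajb9, with the smallest p of the list, was at 0.30 ± 0.07. None of them passed, and 0 genes of the list changed by either adjustment. Camera adjusted p was 2.5e-06, 1.18e-17 and 0.0167 in that order, and adjusted p was 0.629, 0.629 and 0.442 with an estimated correlation. With the Y-linked level as a term, 13 cholesterol genes fell and 1 rose, 69 ribosomal protein genes fell, and 15 stress response genes fell and 1 rose. No list passed with an estimated correlation in either model, and fry passed 1, the p53 targets (adjusted p = 0.00067). Other splits of the same 6 libraries into 3 and 3 gave from 3 to 12 passing lists by camera.

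Among genes linked to senescence, Ccnd1, which encodes cyclin D1, rose from 342 ± 52.6 to 572 ± 13.4 CPM (SD, n = 3; log2 fold change 0.74 ± 0.13, SE; edgeR adjusted p = 0.045). Cdkn1a, Cdkn2a and Cdkn2b, which encode other kinase inhibitors, had log2 fold changes of 0.69 ± 0.16, 0.39 ± 0.08 and 0.60 ± 0.12 (edgeR adjusted p = 0.0675, 0.0627 and 0.0548) without passing. Lmnb1 and Hmgb2, nuclear proteins used as senescence markers, were at −0.85 ± 0.24 and −0.94 ± 0.27 (adjusted p = 0.0879 and 0.0931, edgeR). With the Y-linked level as a term, these 5 genes and Mki67 passed in the same directions. Ccne1, which encodes cyclin E1, was at 0.02 ± 0.23 and did not pass in either model.

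Secreted factor genes went both ways. Timp2, an inhibitor of matrix proteases, rose by 1.17 ± 0.10 on the log2 scale (SE), Plat fell, and the chemokine gene Cxcl14 was at 69.8 ± 30.8 and 212 ± 27.01 CPM (SD, n = 3) with a log2 fold change of 1.60 ± 0.30 (SE; edgeR adjusted p = 0.0506). Il6 was near 1 CPM in both groups, at 0.903 ± 0.287 and 1.30 ± 0.45 CPM, and Igfbp3 had a log2 fold change of 0.55 ± 0.91, with a spread within groups that followed the Y-linked level: it was at 172 and 187 CPM in the libraries numbered 1 and at 21.9 to 86.8 CPM in the others. The secreted cytokine list (adjusted p = 0.667, camera) and the secreted protease list (0.506) did not pass. Once the Y-linked level was a term, 11 secreted protease genes rose and 3 fell, and that list passed (camera adjusted p = 0.031, or 0.662 with an estimated correlation). Of the 26 secreted cytokine genes 5 rose and 6 fell in that model, and their list did not pass (camera adjusted p = 0.599). Among all genes, 4761 of 13990 passed in that model. Cxcl14 and Igfbp3 passed in it (edgeR adjusted p = 0.00172 and 0.0457), both higher in p27OE, and Il6 did not.

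Interferon response genes did not pass (camera adjusted p = 0.985, median 0.03 and mean −0.06). Their medians stood apart in EV control 1 and p27OE 1, at 1.47 and 1.06 log2 units against the control mean. They were at −0.759 to −0.336 in the other 4 libraries. Without EV control 1 the list passed (camera adjusted p = 0.0376), with p27OE 1 then the only library of high median. Without both libraries numbered 1 the list did not pass (camera adjusted p = 0.211). Over all 6 libraries its adjusted p was 0.991 with an estimated correlation and 0.91 with fry. H2-D1, a class I antigen presentation gene with closely related copies, which makes its count uncertain, rose by 0.52 ± 0.08 (SE), in a list with a camera adjusted p of 0.11, and 0.0173 without EV control 1; over all 6 libraries its adjusted p was 0.944 with an estimated correlation, and 0.794 with the Y-linked level as a term as well. The YAP and TEAD target genes Lats2, Ptpn14 and Tgfb2 rose, Lats2 by 0.71, Ptpn14 by 0.61 and Tgfb2 by 0.55, in a list with a camera adjusted p of 0.24, and 0.0486 without p27OE 1. Of its 18 genes, 11 rose and 2 fell with the Y-linked level as a term (camera adjusted p = 0.00703; adjusted p = 0.662 with an estimated correlation). Gsr, glutathione reductase, fell by 0.64 ± 0.10, while Nqo1 and Me1 were at 0.67 ± 0.17 and 0.44 ± 0.09 without passing. Their oxidative stress list had 11 genes above 0 and 11 below (camera adjusted p = 0.824). The early response gene Nr4a1 rose by 0.61 ± 0.11, while Egr3 was at −0.83 ± 0.18 without passing. Their list had 5 genes above 0 and 11 below (camera adjusted p = 0.667). Smooth muscle contractile genes had 19 of 20 members above 0 (median 0.29, camera adjusted p = 0.0533, 0 changed). The adjusted p of that list was 0.944 with an estimated correlation and 0.689 with fry; by camera it was 0.0277 to 0.0387 with no filter, total counts or upper-quartile scaling, 0.502 without EV control 1, 0.633 without p27OE 3, 0.0111 without both libraries numbered 1, and 0.000143 to 0.0384 without any one of the other libraries. Its genes rose in 16 cases with the Y-linked level as a term, and the camera adjusted p was 2.5e-07, with an adjusted p of 0.662 with an estimated correlation. Kinase inhibitor and pocket protein genes (camera adjusted p = 0.809), extracellular matrix genes (0.985) and complement genes (0.489) did not pass.

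Markers of other cell types did not pass as lists in the model with the group alone. All 15 macrophage genes lay below 0 with a median of −1.04, none passing, and the list had a camera adjusted p of 0.121. It passed with the Y-linked level as a term (0.00703), without EV control 2 (0.0148) and without EV control 3 (0.0034), was at 0.897 without EV control 1, and did not pass without both libraries numbered 1 (0.463), where its median voom log2 fold change was 0.16 in place of −0.57. The list had an adjusted p of 0.944 with an estimated correlation, or 0.796 with the Y-linked level as a term as well. The summed CPM of these genes was 104.9 in EV control 1 and from 20.7 to 40 in the other libraries. Endothelial genes had a camera adjusted p of 0.554, skeletal muscle genes 0.987, and epithelial, adipocyte, cartilage and bone, and neural genes 0.985 each. The sign of the list test differed from that of the median in skeletal muscle (median 0.33, test down), adipocyte (−0.17, test up), cartilage and bone (−0.29, test up) and neural genes (−0.07, test up). Col10a1 was the 1 called gene of these lists.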

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

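The Y-linked term, its alternatives and the omission of both libraries numbered 1 were chosen after the data were seen. The 365 called genes (80 at 2-fold) became 2321 (316) with DESeq2, 4761 (516) with the Y-linked term and 2334 (451) without both libraries numbered 1. Leaving out each library gave 1 to 1827 (1 to 317), and the cause was not tested apart from the Y-linked term. All 365 were also called in each of the first 3. The replicate number as a block gave 2410 (385); EV control and p27OE libraries of the same number deviated together with r = 0.67, 0.04 and 0.50 across genes, and EV control 2 correlated best with p27OE 3 (0.56), so the numbers were not taken as pairs. Under the block the smooth muscle (camera adjusted p = 0.000468) and macrophage (0.0138) lists also passed. Cdkn1b stayed between 2.48 and 2.97 over the leave-one-out fits. The 7 passing lists became 11 with the Y-linked term, 0 with an estimated correlation, 1 with fry, and 0 with the Y-linked term and an estimated correlation. The 4761 genes were 365 with no term and 2137 to 6257 over the leave-one-out fits. Other scalings, filters and limma-voom gave 313 to 497 genes. No called value reversed; 13 gene values without a call changed sign. In each of 5 leave-one-out fits 34 named genes lost their call. Il6 rests on 36 to 86 counts per library, below the level of the genes changed in simulation. Even for those genes, 1.5-fold changes were mostly missed in the model with the group alone (9% called).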

Other observations

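The genes named here beyond the rule were chosen after their values were seen. Several gene groups differed between the libraries of low and high Y-linked level in both treatments. Each group has 1 low-level library, the one numbered 1, so level and number are hard to tell apart. In p27OE 2, intermediate in level, the interferon median was −0.336, near p27OE 3 (−0.558) and far from p27OE 1 (1.06). Its complement median, 0.416, was nearer p27OE 1 (0.487) than p27OE 3 (−0.089). Its matrix and smooth muscle medians, 0.042 and 0.213, also lay between those of the other p27OE libraries. With the group as the other term, 4495 of 13990 genes changed with the Y-linked level (edgeR), 2299 higher and 2196 lower, and 4180 of them lie on autosomes. Of 26 interferon response genes, 25 were lower at a high Y-linked level, with a median of −1.96 log2 units over the full range of the level. Extracellular matrix genes went both ways, with 23 of 38 lower and 7 higher (Thbs1 at 0.62 ± 0.06), the lower ones including the proteoglycan genes Lum (−3.78 ± 0.22, SE) and Dcn (−3.36 ± 0.19) and the elastin gene Eln (−3.78 ± 0.25). Complement genes had 9 of 16 lower and 1 higher, with C4b at −3.93 ± 0.26, while 17 of 20 smooth muscle contractile genes were higher. Of the 38 G2/M genes, 1 was lower and 0 higher, but their medians went opposite ways with the level in the 2 groups, at −0.236 in EV control 1 against 0.155 and 0.088 in EV control 2 and 3, and at −0.597, −0.755 and −1.396 in p27OE 1, 2 and 3.

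Whether the lower G2/M values of p27OE depend on the Y-linked level stays open. A term for such a difference passed for 1299 of 13990 genes (edgeR), 37 of the 38 G2/M genes among them, but it was added after those medians were seen and rests on 1 low-level library per group, so it restates them and is no independent test. Cdkn1b was also higher in the p27OE library with the high level.

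The tests of the Y-linked term against the amount of Cdkn1b, of the hypoxia genes against library composition, and of the histone genes against shared reads and S phase were chosen only after the results were seen. The 3 against 3 design has 10 splits, too few for a share under 0.05. For the 365 genes, 1 of 10 splits, the real one, gave as many, with 0 as the highest other; for the 80 genes it was 1 of 10 with 0, and for the 4761 genes 1 of 10 with 0. For the 7 lists 8 of 10 splits gave as many, with 12 as the highest other. The medians of the hypoxia and histone members below had sizes of 0.5 and 0.85, with 0.33 and 0.67 as the highest of the other splits.

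The count of called genes rose from 365 to 4761 with the Y-linked level as a term. Against any covariate raising the count alike, 0 of 100 random reassignments of the levels called as many. The highest, 4758, was a near copy of the real levels. Among the assignments correlated with them at 0.95 or less the highest was 2597. The level was chosen after the data were seen and split the libraries as the first principal component did. The reassignments therefore cannot tell it from another term along that axis. A term for library total called 1 gene, against sequencing depth. The deviations of EV control 1 and p27OE 1 correlated at 0.67 across genes, which a p27OE-only difference in Cdkn1b would not give to a control library. That does not exclude a part for the amount of Cdkn1b. It was at 167, 232 and 337 CPM in p27OE 1, 2 and 3, where the summed Y-linked CPM was 1.95, 57.15 and 137.26. A separate batch for the libraries numbered 1 stays open, since that term called 3077 genes. The spread may come from cultures of male and female embryos, or a mix of them, but embryo of origin and sex cannot be told apart here.

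Genes of hypoxia and glycolysis were lower in p27OE cells. Egln3, Pdk1, Bnip3 and Mif were among the members seen first (log2 fold changes −1.48, −1.07, −0.91 and −0.84). Of the members not yet seen, 37 of 37 lay below 0 with a median of −0.5. The camera p of these members was 7.99e-13, and 0.105 with an estimated correlation. They were measured in the same libraries as the members that prompted the list, so this was no independent test. Egln1 and Fam162a fell over all genes. With the Y-linked level as a term, the median stayed at −0.48 and 26 of 37 fell. The level ran from 0.1% to 91.8% of the highest library in EV control and from 1.4% to 100% in p27OE. With such overlap, the term could move the group difference little. A shift with the level that is alike in both groups did not account for the lower values. One that differs between the groups is not covered by this term. Oxygen and culture density may differ between the groups and were not tested.

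Histone cluster genes were higher in p27OE cells, from Hist1h4h (3.12 ± 0.33, SE) and Hist1h2bc (1.11 ± 0.15), seen first. Of 24 members not seen first, 21 lay above 0 with a median of 0.85, but 18 averaged under 1 CPM in EV control and the median of the 6 others was 0.44. The camera p was 0.000251, and 0.188 with an estimated correlation, and Hist1h2be and Hist1h1c rose. These members came from the same libraries as those seen first, so this was no independent test. Moves of reads between copies cancel in the CPM summed over all histone symbols. That sum was 95.3, 100.1 and 97.2 in EV control and 150.4, 182.1 and 222.6 in p27OE, so such moves did not account for the higher total. CPM summed over 66 symbols without Hist1h2bc and Hist1h1c was 27.4 ± 4.6 in EV control and 49.4 ± 12.7 in p27OE (SD, n = 3), a ratio of 1.8. Reads moved from those 2 genes could raise this second sum, so it cannot exclude shared reads for the members near 1 CPM. A change in the share of S-phase cells would move these genes with the G1/S list only if the histone reads counted here follow S phase. The G1/S median was −0.67 against 0.85 here, or 0.44 in the 6 members at 1 CPM or more. Whether these reads follow S phase was not tested, so the opposite signs do not decide the question. Polyadenylated histone transcripts in cells that leave the cycle are a candidate source, which was not tested.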
